A study of Mus musculus with 29 samples.

How the data were processed

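RNA was measured in 29 libraries of mouse macrophages. The submitters' notes state that RNA was extracted with the RNeasy Mini Kit, that libraries were made by BGI for the DNBseq platform, and that STAR, HTSeq and the mm10 genome build were used. The versions, the annotation and the strand setting of the counting step are not given in the sources used here. The deposited table holds a raw read count per Ensembl gene and library, whole numbers with no normalization, for 53379 gene identifiers. Of these identifiers, 53274 matched GENCODE M21 (GRCm38, the same assembly as mm10), which gave symbols, positions and exons, and 105 did not.

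Each gene was checked for exons that overlap an annotated exon of another gene on the opposite strand. Such overlap was found for 9020 genes, or 16.9% of those matched. These genes took 94.0% of all counts of the marrow-derived macrophages and 74.9% of those of the peritoneal macrophages, so values of an overlapping gene are given with its partner, and every comparison was also fitted on genes without opposite-strand exons alone. That second fit was chosen after the data were seen.

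Libraries were grouped by the labels alone. Counts were analysed in R 4.3.3 with edgeR 4.0.16 in 2 fits, a model of 8 group means for the 20 libraries of marrow-derived macrophages and a model of 4 group means for the 9 libraries of peritoneal macrophages. Low counts were removed with filterByExpr by group, which left 6269 and 11771 genes (2448 and 6701 in the fits without opposite-strand exons). Library sizes were scaled by TMM, dispersions were estimated with estimateDisp and robust glmQLFit, and each contrast was tested with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Adjusted p values of genes are from edgeR unless DESeq2 is named. Levels are CPM values computed with TMM factors, given as mean ± SD, and changes are log2 folds ± SE, with the SE taken from the fold and its F statistic. Where all libraries of 1 group had no count, the fold is a lower bound computed against 3 counts over the group. Where a group held 1 to 3 counts in all, and for Gls, the ratio of CPM pooled over libraries is given with its 95% exact counting interval. No fold is given where both groups were at or under the floor. The labels do not state whether replicates came from separate animals, so p values measure only the spread between samples.

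Gene lists were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of alternatives. The 25 lists were alternative activation, inflammatory NF-kB targets, the interferon response, amino acid stress (Atf4 targets), glutamine metabolism, the TCA cycle, nuclear oxidative phosphorylation genes, the mitochondrial genome, cholesterol synthesis, LXR targets, efferocytosis, lipid-associated macrophages, matrix repair, glycolysis and hypoxia, the cell cycle, Nrf2 and redox genes, and markers of large peritoneal macrophages, small peritoneal macrophages and monocytes, T and NK cells, B cells, neutrophils, dendritic cells, mast cells and eosinophils, mesothelium and fibroblasts, and erythroid cells. Each list with at least 3 measured members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists of that comparison, and again with an estimated correlation. This gave 18 tested lists in marrow-derived and 23 in peritoneal macrophages. Members were also counted by the call over all genes and by a p value adjusted over the list alone.

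Named genes followed a rule. In each comparison, it took the called genes with an average log2 CPM of at least 2 and no overlap between the libraries of the 2 groups, and from these the 10 largest rises and the 10 largest falls, without clone or model names. It added up to 4 called members of each list with the smallest p. Gls, Gls2 and Glul were always included, with Arg1, Retnla, Chil3 and Mrc1 in marrow-derived and Ldlr, Gata6, Timd4, Mertk and Abca1 in peritoneal macrophages. The text prints a part taken from the top of each part of the rule. Members given as examples of a list that was called without at least 2 called members, and the short lists of called genes with clone or model names, were chosen after their values were seen.

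The alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, leaving out each library of the compared groups in turn, the replicate number as a block (overall and within genotype, for marrow-derived macrophages), a fit of only the 2 groups compared, and the estimated correlation for lists. After the data were seen, the fit without opposite-strand exons was added, and a fit without the 4 Gls1-null marrow-derived libraries that had Ddx3y counts and no Xist count. Where leaving out a library left a group with 1 library, that library was assumed to vary like the other groups. The procedure was tested on simulated counts drawn with the depth and dispersion of 3 comparisons, with 50 genes changed at each size. Recovery at a log2 fold of 1 and -1 was 36% and 36% for IL-4 in control cells, 36% and 38% for Gls1-null against control cells with IL-4, and 14% and 6% for the recipients of Gls1-null marrow. At 2 and -2, it was 82% and 60%, 88% and 62%, and 88% and 60%. False calls numbered 6, 4 and 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sample was left out.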

Results

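RNA of mouse macrophages was sequenced to ask how glutaminase, the enzyme that turns glutamine into glutamate, affects their restorative functions in atherosclerosis. The table held 20 libraries of bone marrow-derived macrophages, grown from Gls1-null or control mice, and 9 libraries of peritoneal macrophages from mice transplanted with marrow. The marrow-derived cells were kept for the last 24 h with interleukin 4 (IL-4), which drives alternative activation, with MSO, an inhibitor of glutamine synthetase, with both, or with neither. The basal and MSO groups had 2 libraries per genotype, and the IL-4 and IL-4 with MSO groups had 3. The peritoneal macrophages came from Ldlr-null recipients that were labelled Gls2-intact or Gls2-null and were given marrow labelled control or Gls1-null, after 11 weeks of Western diet. These groups had 2 libraries each, except for the Gls2-null recipients of control marrow with 3. The total count per library was 1243260 to 1419120 in marrow-derived and 1692980 to 1971770 in peritoneal macrophages, and 10014 to 12600 and 17743 to 18527 genes had a count. Intervals and floors cover counting error only. The p values measure only the spread between samples, since the labels do not state whether replicates were separate animals. The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined.

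Most counts of the marrow-derived macrophages lay in genes that share exon positions with a gene on the opposite strand. These genes took 89.4% to 95.8% of the counts of each marrow-derived library and 72.7% to 79.4% of each peritoneal library. They hold 27.5% of exon bases, and the overlap 3.25%. Gm10252, a gene of no known function on chromosome 7 (mm10 positions 45459469 to 45460300), overlaps 355 bp of Ftl1, which encodes the light chain of ferritin, and took 16.9% to 26.5% of the counts of each marrow-derived library. Ftl1 itself had 363 to 1789 counts. Mt-Nd6, the only protein gene on the light strand of the mitochondrial genome, had 172 to 823 times the counts per kilobase of the heavy-strand genes in marrow-derived and 40.0 to 127 times in peritoneal macrophages. Values of genes with such a partner are therefore uncertain between the 2 strands, and the partner is given. CPM of genes without a partner is uncertain too, because the strand setting is not stated, and marrow-derived libraries had only 59 to 381 counts of Lyz2. Levels of such genes may therefore rest on residual counts. Genes without opposite-strand exons held 50185 to 139637 counts per marrow-derived library and 344976 to 534568 per peritoneal library. Basal Gls1-null replicate 2 stood apart with 10.3% of its counts in such genes, and the other 19 marrow-derived libraries had lower shares.

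**Figure D1:**
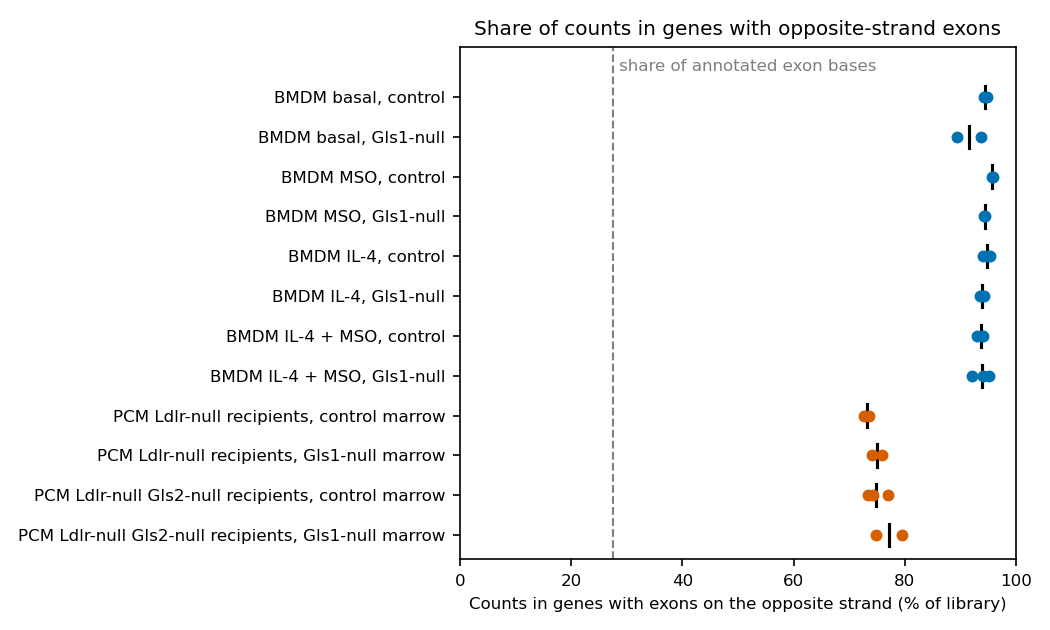
Share of each library's counts (%) in genes with opposite-strand exons, by group. The 20 marrow-derived libraries sit between 89.4% and 95.8%, and the 9 peritoneal libraries between 72.7% and 79.4%.

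The deleted gene was examined first. Gls (ENSMUSG00000026103, chromosome 1, 52163448 to 52233232, no opposite-strand exons) encodes kidney-type glutaminase, the product removed in Gls1-null cells. It had 49 counts over the 10 control marrow-derived libraries and 17 over the 10 Gls1-null libraries, a CPM ratio of 0.333 (95% exact interval 0.180 to 0.588). Single libraries had 2 to 8 counts in controls and 0 to 6 in Gls1-null cells, with the highest Gls1-null count, 6, in MSO replicate 2. The ratio was 0.488 (0.105 to 1.92) in basal cells, 0.442 (0.136 to 1.27) with MSO, 0.296 (0.0704 to 0.959) with IL-4 and 0.193 (0.0362 to 0.667) with IL-4 and MSO, so that the intervals without IL-4 included equality. In peritoneal macrophages Gls had 49 to 96 counts per library (30.4 to 49.6 CPM). Labelled Gls1-null marrow gave log2 folds of -0.07 ± 0.25 in Gls2-intact and 0.04 ± 0.23 in Gls2-null recipients. Gls2, which encodes liver-type glutaminase and overlaps Spryd4 by 97 bp, had 3 to 15 counts per peritoneal library, and its log2 fold in labelled Gls2-null against Gls2-intact recipients was 0.12 ± 0.65 with control marrow and -0.31 ± 0.70 with Gls1-null marrow. Both peritoneal genotypes are therefore given as labelled. Glul, which encodes glutamine synthetase, the target of MSO, overlaps Teddm2 by 116 bp and was not called in any comparison.

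The comparison of IL-4 with basal control cells (n = 3 and 2) asked which genes alternative activation changed. IL-4 raised the hallmark genes of alternative activation. Arg1, which encodes arginase (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), rose from 0.372 ± 0.526 to 25.0 ± 14.5 CPM, a ratio of 67.0 (95% exact interval 11.7 to 2674, adjusted p = 6.24e-08). Egr2, a transcription factor induced by IL-4 through Stat6 (ENSMUSG00000037868, chromosome 10, 67535475 to 67542188), rose by 3.88 ± 0.56 on the log2 scale from 1.86 ± 2.63 to 29.1 ± 4.65 CPM, with no count in basal control replicate 2. Retnla, which encodes the secreted protein Fizz1, rose at least 10.3-fold, and Itgax, an integrin of tissue macrophages, at least 13.2-fold. Clec7a, the receptor for fungal glucans (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779), rose from 8.27 ± 4.09 to 41.9 ± 11.9 CPM (log2 fold 2.32 ± 0.39, adjusted p = 1.29e-05). Atp6v0d2, a subunit of the lysosomal proton pump with a role in macrophage fusion, rose from 4.14 ± 1.51 to 40.1 ± 6.78 CPM (3.24 ± 0.46). Mrc1, the mannose receptor, rose from 22.7 ± 0.529 to 75.3 ± 23.1 CPM (adjusted p = 0.00303, and 0.064 without basal control replicate 1). Ctsd, a lysosomal protease, fell from 655 ± 29.1 to 355 ± 72.1 CPM (-0.88 ± 0.18).

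In all, 215 genes rose and 139 fell in control cells, of which 274 have opposite-strand exons. The fit of genes without them called 50 rises and 21 falls. The total of 354 was 208 and 226 without basal control replicates 1 and 2. Of 34 named genes called, 15 kept their call whichever library was left out. Of the 13 measured genes of alternative activation, 8 rose and 0 fell (9 when adjusted over the list alone), with a median log2 fold of 2.40 (adjusted p = 1.11e-12, and adjusted p = 0.00836 with an estimated correlation), which was 3.65 without basal control replicate 1. Of 8 markers of small peritoneal macrophages and monocytes, 3 rose, among them Cd74, which encodes a chaperone of MHC class II (median 1.53, adjusted p = 0.00414, adjusted p = 0.205 with an estimated correlation). That list was not called without basal control replicate 2 (1.05, 0.0702), nor was Cd74 (1.52, adjusted p = 0.254). Cd74 was also lost without IL-4 control replicate 1 (1.49, 0.158), and had a log2 fold of 3.57 without basal control replicate 1. No other list was called. The efferocytosis genes, which serve the uptake of dead cells, had 1 rise and 3 falls among 19 (median -0.40, adjusted p = 0.298), with falls of the scavenger receptor genes Stab1, which overlaps Nt5dc2, and Lrp1. These falls were not called without basal control replicate 2 (Stab1, adjusted p = 0.118) or 1 (Lrp1, 0.146). Lipid-associated macrophage genes had 3 rises and 2 falls among 17, with a median of -0.31 and a mean of 0.38, which differ in sign, and an adjusted p of 0.733.

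The remaining lists were not called in that comparison. Their median log2 folds were -0.77 for inflammatory NF-kB targets, -0.50 for the interferon response, 0.20 for amino acid stress, -0.38 for glutamine metabolism, 0.21 for the TCA cycle, 0.05 for oxidative phosphorylation and -0.18 for cholesterol synthesis. They were -0.49 for LXR targets, 0.15 for matrix repair, -0.11 for glycolysis and hypoxia, 0.08 for the cell cycle, -0.43 for Nrf2 and redox genes and 0.16 for markers of large peritoneal macrophages. The mitochondrial genome had a median of -0.02 and a mean of 0.04, which differ in sign. Only 2 neutrophil markers were measured (median 1.91, not tested). No member of the lists of T and NK cells, B cells, dendritic cells, mast cells and eosinophils, mesothelium and fibroblasts, or erythroid cells passed the filter in marrow-derived cells.

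**Figure D2:**
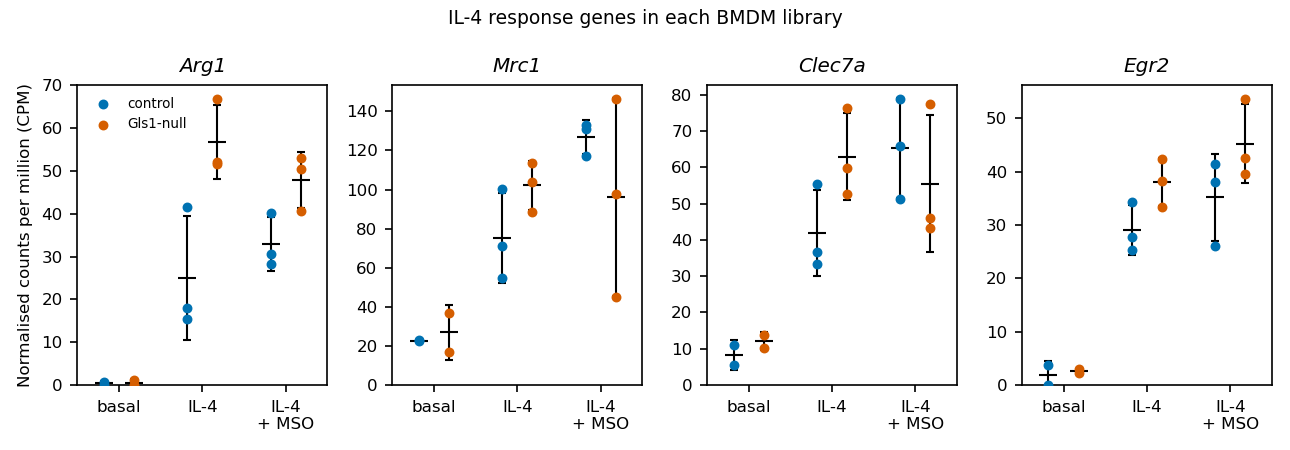
CPM (vertical axis) of Arg1, Mrc1, Clec7a and Egr2 in each basal, IL-4 and IL-4 with MSO library of both genotypes, with the mean and SD of each group. Arg1 was 25.0 ± 14.5 CPM in control and 56.9 ± 8.65 CPM in Gls1-null cells with IL-4.

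In Gls1-null cells (n = 3 and 2), the same comparison asked whether the response to IL-4 was present without Gls1. IL-4 raised the same hallmark genes there. Arg1 rose from 0.574 ± 0.812 to 56.9 ± 8.65 CPM, a ratio of 87.9 (95% exact interval 24.0 to 730), and Egr2 from 2.63 ± 0.465 to 38.0 ± 4.52 CPM (3.83 ± 0.51). Clec7a rose from 12.1 ± 2.43 to 62.9 ± 12.1 CPM, and Mrc1 from 26.9 ± 14.0 to 102 ± 12.6 CPM (1.89 ± 0.35, adjusted p = 3.49e-04). Retnla rose by a ratio of 36.6 (9.85 to 307). Ctsd fell by 1.28 ± 0.17 on the log2 scale, and Ccl3, which encodes an inflammatory chemokine, by 1.87 ± 0.29. The integrin gene Itgb5 fell from 59.5 ± 10.0 to 16.7 ± 1.60 CPM, and Lrp1 from 187 ± 2.06 to 73.3 ± 15.1 CPM (-1.35 ± 0.23).

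In all, 407 genes rose and 251 fell in Gls1-null cells, 496 of them with opposite-strand exons, and the fit of genes without them called 81 rises and 38 falls. The total of 658 was 298 without the libraries with Ddx3y counts, 310 without basal Gls1-null replicate 2 and 734 without replicate 1. Leaving out replicate 2 ended 22 of the 47 named calls, with adjusted p up to 0.452, among them Mertk, a receptor for dead cells (-3.20 ± 0.73, adjusted p = 0.0888 without it), and its ligand gene Gas6, which overlaps Tmem255b (adjusted p = 0.268 without it). Alternative activation again had 8 rises and 0 falls (9 adjusted over the list alone), with a median of 2.36 (adjusted p = 9.54e-12, and adjusted p = 0.015 with an estimated correlation). Efferocytosis genes had 1 rise and 6 falls, with a median of -0.65 (adjusted p = 0.00425, adjusted p = 0.334 with an estimated correlation), and the call was lost among genes without opposite-strand exons (-0.08, 0.0825) and without the libraries with Ddx3y counts (-0.28, 0.162). Leaving out basal Gls1-null replicate 2 moved its median to -0.41. Markers of small peritoneal macrophages and monocytes had 3 rises (median 0.70, adjusted p = 0.0354, adjusted p = 0.334 with an estimated correlation). This list was not called without basal Gls1-null replicate 1 (0.54, 0.0707) or IL-4 Gls1-null replicate 2 (0.38, 0.0682), and its median was 1.24 without basal Gls1-null replicate 2. LXR targets, which export cholesterol, had 3 falls and a median of -0.83 (adjusted p = 0.0508), and were called among genes without opposite-strand exons (-0.98, 0.00165), as was the mitochondrial genome (0.58, 0.0150). Matrix repair genes had 4 rises, with a median of -0.10 and a mean of 0.62, which differ in sign.

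The genotype by IL-4 interaction asked whether the response differed between genotypes. With edgeR, it called 0 genes (307 at an unadjusted p under 0.05), DESeq2 called 0, and no list was called. Without basal Gls1-null replicate 1 it called 9. The alternative activation list had a median interaction of 0.04 and a mean of -0.47, which differ in sign (adjusted p = 0.544). Of the genes called in control and Gls1-null cells, 177 rises were shared (14.0 by overlap at random) and 96 falls (5.57). Across the 739 genes called in either genotype, the log2 folds correlated with Pearson's r = 0.848 and Spearman's rho = 0.865, and 28 differed in sign. Across the 135 such genes without opposite-strand exons, r was 0.852 and rho was 0.808. Genes are not independent replicates, so no p is given for these 2 correlations.

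**Figure D3:**
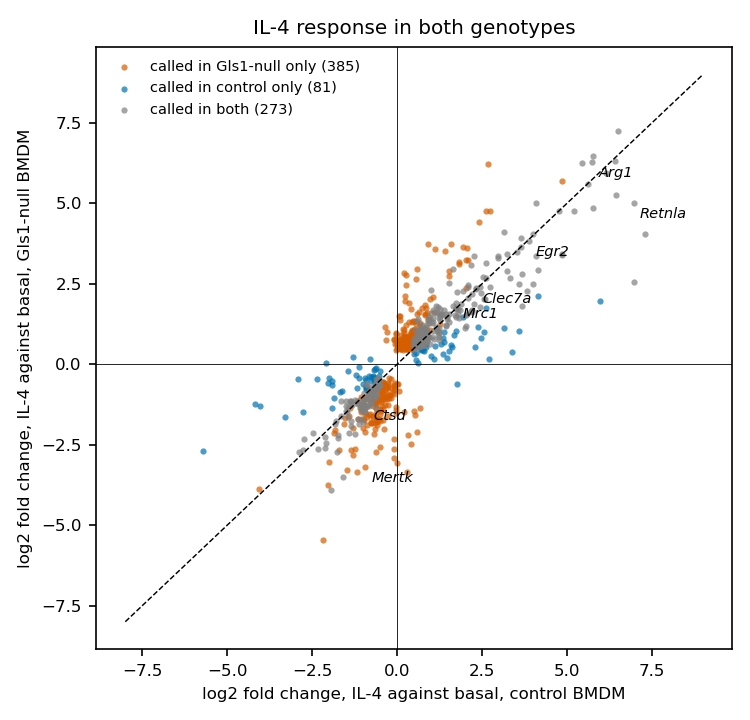
Log2 fold of IL-4 against basal in control (horizontal axis) and Gls1-null cells (vertical axis) for the genes called in either, with genes called in both marked. The folds correlated with r = 0.848 across 739 genes, and 28 genes had opposite signs.

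Gls1-null and control basal cells (n = 2 and 2) were compared for the effect of genotype without stimulation. Few genes were called at this depth, where 1 gene rose and 4 fell (776 at an unadjusted p under 0.05). Emilin2, which encodes an extracellular matrix glycoprotein, rose from 6.39 ± 3.60 to 32.0 ± 0.652 CPM (adjusted p = 0.0492), but was not called without basal control replicate 2 (adjusted p = 0.709) or 1 (0.0533), or basal Gls1-null replicate 2 (0.178). The smallest adjusted p was that of a fall of Gm10602, an antisense gene of unknown function that overlaps 1204 bp of the phosphatase gene Inppl1 (-0.97 ± 0.17, adjusted p = 0.00252). All 4 falls have opposite-strand exons, and short call lists were read after their values were seen. The number of calls was 192 without basal Gls1-null replicate 1 (46 rises and 146 falls), 7 without basal control replicate 1, 1 without basal Gls1-null replicate 2 and 0 without basal control replicate 2. It was 21 with DESeq2 and 16 without a filter. Arg1, Retnla and Mrc1 were not called.

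The basal lists lay above the other genes in Gls1-null cells together with a shift between the gene classes. The median log2 fold was 0.43 over genes without opposite-strand exons and -0.15 over genes with them, and the first class held 8.17 ± 3.05% of counts in Gls1-null and 5.19 ± 0.468% in control cells. Higher medians were found for glycolysis and hypoxia (0.65, adjusted p = 4.28e-05, 8 members adjusted over the list alone), lipid-associated macrophages (0.54, 7.52e-05, 6 members), Nrf2 and redox genes (0.49, 0.00605), the TCA cycle (0.73, 0.0155), efferocytosis (0.44, 0.0267) and small peritoneal macrophages and monocytes (1.19, 0.00605). None of the 6 was called with an estimated correlation (adjusted p = 0.263 to 0.424 with an estimated correlation) or among genes without opposite-strand exons (0.0513 to 0.412). Examples, chosen after their values were seen, were Ldha, which makes lactate (1.00 ± 0.28, adjusted p = 0.159), and Gpnmb, a lysosomal glycoprotein of lipid-laden cells (0.57 ± 0.19, adjusted p = 0.235). Leaving out basal Gls1-null replicate 2 ended the calls of the TCA cycle (0.42, adjusted p = 0.231), efferocytosis (0.09, 0.476), Nrf2 and redox genes (0.35, 0.244) and small peritoneal macrophages and monocytes (0.54, 0.109), and moved glycolysis to 0.31 and lipid-associated macrophages to 0.25. Basal control replicate 2 ended those of efferocytosis (0.25, 0.204), Nrf2 and redox genes (0.32, 0.0841) and small peritoneal macrophages and monocytes (0.64, 0.204), and basal control replicate 1 that of the TCA cycle (adjusted p = 0.189), with an efferocytosis median of 0.72. The glycolysis median was 1.00 without basal control replicate 1 and 1.13 without basal Gls1-null replicate 1.

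With IL-4, Gls1-null cells were compared with control cells (n = 3 and 3) for the effect of Gls1 on alternative activation. Lyz2, which encodes the lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), fell from 128 ± 6.40 to 68.1 ± 21.2 CPM (-0.91 ± 0.19, adjusted p = 0.0218). Plek, a substrate of protein kinase C that overlaps Cnrip1, fell from 379 ± 73.9 to 224 ± 14.5 CPM, and Stab1 from 378 ± 57.9 to 253 ± 8.19 CPM. Flna, an actin crosslinker, rose from 31.6 ± 8.26 to 64.5 ± 2.81 CPM, although it was not called among genes without opposite-strand exons (adjusted p = 0.192), and Aldoa, a glycolytic enzyme that overlaps Fam57b, rose from 125 ± 23.4 to 207 ± 29.0 CPM. Arg1 was 56.9 ± 8.65 CPM in Gls1-null and 25.0 ± 14.5 CPM in control cells and was not called (1.17 ± 0.31, adjusted p = 0.0742). Retnla (1.00 ± 0.47, adjusted p = 0.452) and Mrc1 (0.44 ± 0.28, 0.659) were not called either.

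In all, 8 genes rose and 16 fell, 22 of them with opposite-strand exons. The fit of genes without them called 0 rises and 2 falls, of Lyz2 and of the sterol-binding protein gene Osbpl11. None of the 14 named calls held in every omission. The call of Lyz2 was lost without IL-4 control replicate 2 (adjusted p = 0.0996) or 3 (0.0882), or IL-4 Gls1-null replicate 1 (0.217) or 2 (0.0944). The total of 24 was 88 in a fit of only the 2 groups, 45 with DESeq2 and 44 without a filter, 4 and 5 without IL-4 control replicates 2 and 3, 5, 2 and 5 without IL-4 Gls1-null replicates 1, 2 and 3, and 46 without IL-4 control replicate 1. The named genes that lost their call reached adjusted p values of 0.401 and 0.197 without those 2 control libraries and 0.217, 0.26 and 0.253 without the 3 Gls1-null libraries.

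In the same comparison, the list medians again lay above the other genes while genes without opposite-strand exons had a median log2 fold of 0.23 and those with them -0.04, with 5.83 ± 0.390% against 4.92 ± 0.666% of counts in the first class. Nrf2 and redox genes, which supply NADPH and glutathione, had 14 of 16 members above 0 and 4 called when adjusted over the list alone (median 0.64, adjusted p = 7.81e-05, adjusted p = 0.154 with an estimated correlation), and kept their call among genes without opposite-strand exons (0.58, 1.12e-04). Examples, chosen after their values were seen, were Pgd, an enzyme of the pentose phosphate pathway (0.98 ± 0.25, adjusted p = 0.052), and Tkt (1.36 ± 0.42, 0.149). Glycolysis and hypoxia (0.41), matrix repair (0.33), lipid-associated macrophages (0.40), small peritoneal macrophages and monocytes (0.70) and alternative activation (0.39) were also higher, with adjusted p = 8.78e-04 for the first 3, 0.00226 and 0.0372 for the others and adjusted p = 0.154 to 0.318 with an estimated correlation. Among genes without opposite-strand exons, glycolysis (adjusted p = 0.128) and lipid-associated macrophages (0.121) were not called, and the interferon response (-0.47, 0.00953) and LXR targets (-0.39, 0.0170) were. The lipid-associated list was lost without IL-4 control replicate 2 (0.23, adjusted p = 0.0984), and its median was 0.20 without IL-4 control replicate 3 and 0.17 without IL-4 Gls1-null replicate 2. Alternative activation was lost without IL-4 control replicate 2 (adjusted p = 0.185) or IL-4 Gls1-null replicate 2 (0.063) or 3 (0.0823). Matrix repair had a median of 0.68 without IL-4 control replicate 1, and small peritoneal macrophages and monocytes one of 0.45 without IL-4 control replicate 2.

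With MSO alone, Gls1-null cells were compared with control cells (n = 2 and 2) for the effect of Gls1 when glutamine synthesis was inhibited. Genes of the mitochondrial genome were higher in Gls1-null than in control cells. Mt-Cytb, a subunit of complex III (ENSMUSG00000064370, mitochondrial genome, 14145 to 15288), rose from 38.9 ± 0.781 to 133 ± 21.7 CPM (1.78 ± 0.23, adjusted p = 9.72e-07). It was the only named gene of 24 that kept its call in every omission. The complex I subunits mt-Nd1 (1.13 ± 0.23) and mt-Nd5 (0.80 ± 0.19, overlapping mt-Nd6) and mt-Co1 of complex IV (0.91 ± 0.19, overlapping mt-Ts1) also rose. Atp1a1, a subunit of the sodium pump, rose from 16.1 ± 0.0362 to 51.4 ± 2.25 CPM (adjusted p = 0.00526). The falls included Psmb9, a subunit of the immunoproteasome that overlaps Tap1 (-0.89 ± 0.22).

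Of 22 rises and 24 falls with MSO, 35 genes have opposite-strand exons, and the fit of genes without them called 5 rises and 9 falls. The total of 46 was 74 with DESeq2, 95 without the libraries with Ddx3y counts, 2 and 27 without MSO control replicates 1 and 2, and 5 and 28 without MSO Gls1-null replicates 1 and 2. MSO control replicate 1 and MSO Gls1-null replicate 1 each ended 23 of the 24 named calls (adjusted p up to 0.466 and 0.519), MSO control replicate 2 ended 16 and MSO Gls1-null replicate 2 ended 14 (up to 0.241 and 0.186). All 9 measured genes of the mitochondrial genome lay above 0, with 4 rises and 8 adjusted over the list alone (median 0.82, adjusted p = 3.99e-12, and adjusted p = 0.00401 with an estimated correlation), and the list kept its call in every omission. Glycolysis and hypoxia (0.71, adjusted p = 3.01e-04), small peritoneal macrophages and monocytes (1.51, 0.00128), lipid-associated macrophages (0.47, 0.00846) and Nrf2 and redox genes (0.60, 0.0412) were higher too, with adjusted p = 0.176 to 0.658 with an estimated correlation. Of these, only the small peritoneal macrophage and monocyte list was called among genes without opposite-strand exons (adjusted p = 0.0134, against 0.143, 0.758 and 0.401 for the others). All 4 were lost without MSO Gls1-null replicate 1 (medians 0.55, 1.26, 0.42 and 0.26). Small peritoneal macrophages (1.76) and Nrf2 and redox genes (0.38) were also lost without MSO control replicate 2. Genes without opposite-strand exons had a median log2 fold of 0.38 and held 5.31 ± 0.136% of counts in Gls1-null against 3.94 ± 0.0900% in control cells, and genes with them had a median of -0.08.

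With IL-4 and MSO together, Gls1-null cells were compared with control cells (n = 3 and 3). Mitochondrial genes rose and Lyz2 fell. Mt-Nd5 rose from 261 ± 28.4 to 474 ± 64.5 CPM (0.86 ± 0.15, adjusted p = 4.98e-04), mt-Cytb from 92.8 ± 4.41 to 171 ± 9.11 CPM (0.88 ± 0.17) and mt-Nd3, another complex I subunit, from 17.3 ± 1.68 to 51.1 ± 5.01 CPM (1.56 ± 0.31). Lyz2 fell from 161 ± 15.0 to 79.7 ± 13.0 CPM (-1.01 ± 0.19, adjusted p = 0.00157). These genes were among the 7 of 20 named calls that held in every omission. Mt-Nd4 rose by 0.75 ± 0.17, and was not called without IL-4 with MSO control replicate 2 (adjusted p = 0.172) or Gls1-null replicate 3 (0.111). H2-Q7, a class Ib MHC gene, fell from 31.3 ± 10.1 to 9.13 ± 4.02 CPM, and was not called without IL-4 with MSO control replicate 1 (0.0952) or 2 (0.14) or Gls1-null replicate 1 (0.196) or 2 (0.0521). Retnla was 23.7 ± 12.1 CPM in Gls1-null and 6.69 ± 4.71 CPM in control cells (adjusted p = 0.0618), and was called in the fit of genes without opposite-strand exons (1.89 ± 0.46, adjusted p = 0.0124). Arg1 and Mrc1 were not called.

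Of the 29 rises and 16 falls with IL-4 and MSO, 34 genes have opposite-strand exons, and the fit of genes without them called 13 rises and 3 falls. The total of 45 was 79 in a fit of only the 2 groups, 125 without the libraries with Ddx3y counts, 17 without IL-4 with MSO control replicate 2, 29 without control replicate 3, and 23 without Gls1-null replicate 1. Of 9 measured genes of the mitochondrial genome, 4 rose and all lay above 0 (7 adjusted over the list alone), with a median of 0.81 (adjusted p = 1.89e-13, and adjusted p = 0.00254 with an estimated correlation). The 9 measured interferon response genes lay below 0, with 0 called over all genes and 2 adjusted over the list alone (median -0.81, adjusted p = 3.37e-05, and adjusted p = 0.0181 with an estimated correlation). Examples, chosen after their values were seen, were Bst2, which tethers budding virions (-0.62 ± 0.20, adjusted p = 0.14), and Irf7, the transcription factor that amplifies type I interferon and here overlaps Phrf1 (-1.26 ± 0.36, adjusted p = 0.0945). Both lists kept their calls in every omission and among genes without opposite-strand exons. There, alternative activation (0.65, adjusted p = 0.0163), Nrf2 and redox genes (0.37, 0.00549) and small peritoneal macrophages and monocytes (0.62, 0.00549) were called too. Glycolysis and hypoxia was higher by a median of 0.30 (adjusted p = 0.0314, adjusted p = 0.649 with an estimated correlation). It was lost without control replicate 2 (0.18, adjusted p = 0.265) or 3 (0.27, 0.163) or Gls1-null replicate 2 (0.28, 0.0549) or 3 (0.14, 0.345). Its median was 0.48 without control replicate 1. The share of counts in genes without opposite-strand exons was 5.89 ± 1.55% in Gls1-null and 6.04 ± 0.536% in control cells.

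**Figure D4:**
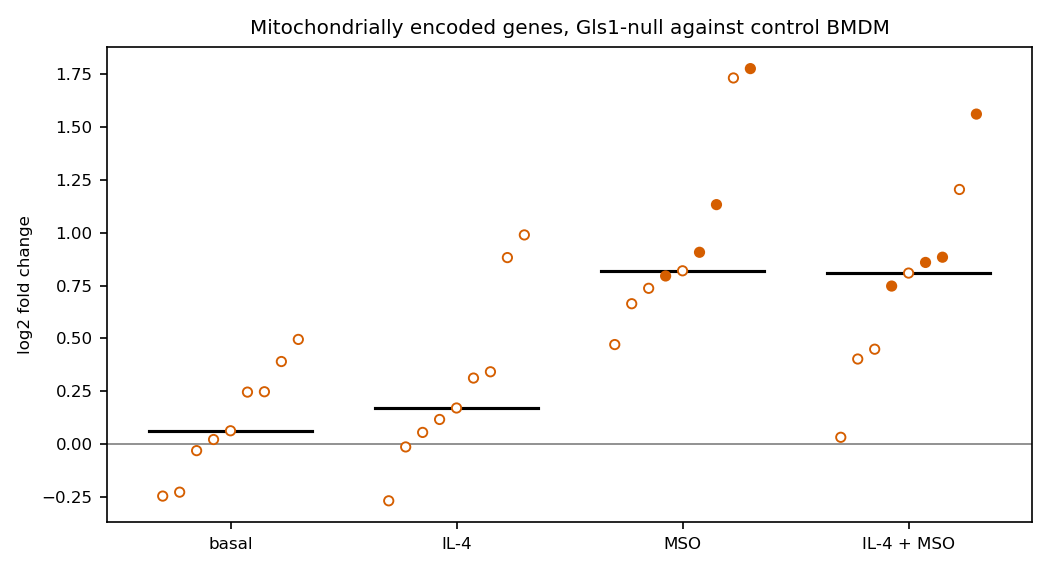
Log2 fold (vertical axis) of 9 mitochondrial genes in Gls1-null against control cells in the basal, IL-4, MSO and IL-4 with MSO comparisons. Filled points were called and lines mark the medians, which were 0.82 with MSO and 0.81 with IL-4 and MSO.

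MSO was compared with no inhibitor in basal cells of each genotype (n = 2 and 2) for the effect of blocking glutamine synthesis. With edgeR, 0 genes were called in control cells (561 at an unadjusted p under 0.05) and 0 in Gls1-null cells (911), where DESeq2 called 0 and 1 and edgeR without a filter 0 and 10. Genes without opposite-strand exons gave 0 calls in control cells and 1 in Gls1-null cells, a rise of Ccdc88a, an actin-binding protein gene (3.38 ± 0.71, adjusted p = 0.00908). Without basal Gls1-null replicate 1, there were 390 calls in Gls1-null cells (272 rises and 118 falls), and without basal control replicate 2 there was 1 in control cells. Glul was not called in control cells (-1.09 ± 0.42, adjusted p = 0.448).

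In control cells, lower medians with MSO were found for lipid-associated macrophages (-0.49, adjusted p = 3.6e-05, 16 of 17 below 0), the mitochondrial genome (-0.65, 1.21e-04, 8 of 9 below 0), LXR targets (-0.61, 0.00845), efferocytosis (-0.58, 0.00845), glycolysis and hypoxia (-0.38, 0.0151) and small peritoneal macrophages and monocytes (-0.78, 0.0387). None was called with an estimated correlation (adjusted p = 0.174 to 0.397 with an estimated correlation) or among genes without opposite-strand exons (0.217 to 0.86). Only lipid-associated macrophages held in every omission, with Lgals3, a galectin of phagocytes (-0.63 ± 0.21), and Ctsb, a lysosomal protease that overlaps Fdft1 (-0.54 ± 0.17), as examples chosen after their values were seen. Basal control replicate 1 ended the calls of the mitochondrial genome (-0.15, adjusted p = 0.109), efferocytosis (0.0927), glycolysis (-0.20, 0.503) and small peritoneal macrophages (-0.23, 0.704). Basal control replicate 2 ended that of LXR targets (0.172) and moved glycolysis to -0.66. MSO control replicate 1 ended those of LXR targets (0.0629), efferocytosis (0.0629) and small peritoneal macrophages (-0.42, 0.0709), and MSO control replicate 2 those of glycolysis (0.146) and small peritoneal macrophages (0.351). The median of the mitochondrial genome was -0.42 without MSO control replicate 2. Genes without opposite-strand exons had a median log2 fold of -0.40 and held 3.94 ± 0.0900% of counts with MSO against 5.19 ± 0.468% without it.

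In Gls1-null cells, MSO lowered the lipid-associated list by a median of 0.67 on the log2 scale (adjusted p = 2.53e-06, adjusted p = 0.242 with an estimated correlation, 7 members adjusted over the list alone), which held in every omission and among genes without opposite-strand exons (-0.30, adjusted p = 0.0209). The mitochondrial genome was higher (0.29, adjusted p = 0.0131, adjusted p = 0.242 with an estimated correlation, 8 of 9 above 0), and was lost without MSO Gls1-null replicate 1 (0.23, 0.062), with medians of 0.44 without basal Gls1-null replicate 1 and 0.57 without MSO Gls1-null replicate 2. The TCA cycle (-0.86, 0.011), oxidative phosphorylation (-0.48, 0.0333), LXR targets (-0.70, 0.00974), efferocytosis (-0.52, 0.00169) and glycolysis and hypoxia (-0.34, 0.0131) were lower, but none of these 5 was called among genes without opposite-strand exons (adjusted p up to 0.956). None of the 7 lists was called with an estimated correlation (up to 0.412). MSO Gls1-null replicate 2 ended the calls of those 5 lower lists (adjusted p = 0.136, 0.278, 0.12, 0.062 and 0.406), and moved the TCA cycle to -0.57 and glycolysis to -0.07. Basal Gls1-null replicate 2 ended those of the TCA cycle (-0.54, 0.0895), oxidative phosphorylation (-0.03, 0.855) and glycolysis (-0.06, 0.557), and moved LXR targets to -0.25 and efferocytosis to -0.21. The glycolysis median was -0.63 without basal Gls1-null replicate 1 and -0.58 without MSO Gls1-null replicate 1, which also moved efferocytosis to -0.79. Genes without opposite-strand exons had a median of -0.43, with 5.31 ± 0.136% of counts with MSO against 8.17 ± 3.05% without it.

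Under IL-4 (n = 3 and 3), MSO was compared with none to ask whether glutamine synthesis mattered for alternative activation. Alternative activation genes were not called with MSO in either genotype. In control cells, 0 genes rose and 10 fell (686 at an unadjusted p under 0.05), 9 of them with opposite-strand exons. The fit of genes without opposite-strand exons called 0, DESeq2 called 35 and a fit of only the 2 groups 19. The smallest adjusted p was that of Taf5, a subunit of TFIID that overlaps Usmg5 (-0.84 ± 0.15, adjusted p = 0.00472). No call was left without IL-4 control replicate 3 (adjusted p up to 0.251 among named genes), IL-4 with MSO control replicate 1 (up to 0.343) or replicate 3 (up to 0.157). Nrf2 and redox genes were higher by a median of 0.58 (15 of 16 above 0, 2 adjusted over the list alone, adjusted p = 2.17e-04, adjusted p = 0.346 with an estimated correlation), with Hmox1, which degrades heme, as an example chosen after its value was seen (0.97 ± 0.34). Lipid-associated genes were higher by 0.34 (17 of 17 above 0, adjusted p = 4.98e-04, adjusted p = 0.504 with an estimated correlation), and were lost without IL-4 control replicate 2 (0.17, 0.157) or IL-4 with MSO control replicate 1 (0.23, 0.102), with a median of 0.58 without IL-4 control replicate 1. Neither was called among genes without opposite-strand exons (adjusted p = 0.167 and 0.871), where the mitochondrial genome was (-0.49, 0.00184). These genes had a median of 0.31 against -0.08 for the others, and held 6.04 ± 0.536% of counts with MSO against 4.92 ± 0.666% without it. In Gls1-null cells, 1 gene rose and 1 fell, both of unknown function and read after their values were seen: Gm47428, which overlaps Ftl1-ps1 (1.03 ± 0.16, adjusted p = 2.18e-04), and Gm45091, which overlaps the transcription factor gene Cebpa (-1.15 ± 0.17, adjusted p = 2.18e-04). The mitochondrial genome was higher by 0.33 (9 of 9 above 0, adjusted p = 1.76e-05, adjusted p = 0.0835 with an estimated correlation), and by 0.21 without IL-4 with MSO Gls1-null replicate 3.

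The genotype by MSO interaction under IL-4 asked whether the effect of MSO depended on Gls1. It called 1 gene, Gm47428 (1.20 ± 0.23, adjusted p = 0.0246), and 0 among genes without opposite-strand exons. DESeq2 called 0. The call was kept without IL-4 control replicate 2 or 3, IL-4 Gls1-null replicate 1 or IL-4 with MSO Gls1-null replicate 3, and was lost in the other 8 omissions. All 9 genes of the mitochondrial genome had an interaction above 0 (median 0.55, adjusted p = 3.12e-04, adjusted p = 0.177 with an estimated correlation). Lipid-associated macrophages had a median of -0.46 (16 of 17 below 0, adjusted p = 8.01e-04, adjusted p = 0.628 with an estimated correlation) and Nrf2 and redox genes one of -0.41 (14 of 16 below 0, 0.0497, adjusted p = 0.628 with an estimated correlation). Among genes without opposite-strand exons, only the mitochondrial genome was called (0.90, adjusted p = 1.48e-06). The lipid-associated list was lost without IL-4 control replicate 2 (adjusted p = 0.132) or IL-4 with MSO control replicate 1 (-0.16, 0.0693), and its median was -0.70 without IL-4 with MSO Gls1-null replicate 3. Nrf2 and redox genes were lost without replicate 2 or 3 of IL-4 control cells (0.274 and 0.194), replicate 1 or 2 of IL-4 Gls1-null cells (0.0829 and 0.128), or replicate 1 or 2 of either IL-4 with MSO group (0.267 and 0.051 in control and 0.0768 and 0.111 in Gls1-null cells). Their median was -0.66 without IL-4 control replicate 1 and -0.65 without IL-4 with MSO Gls1-null replicate 3.

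In peritoneal macrophages, marrow labelled Gls1-null was compared with control marrow for the effect of Gls1 in cells from atherosclerosis-prone mice. No gene was called by edgeR in Gls2-intact recipients (0, with 111 at an unadjusted p under 0.05, n = 2 and 2), where DESeq2 also called 0, or in labelled Gls2-null recipients (0, with 405, n = 2 and 3), where DESeq2 called 4. Without replicate 1 of the Gls2-null recipients of Gls1-null marrow, the second comparison called 24, and without replicate 2 it called 1. Mertk, Gata6, a transcription factor of large peritoneal macrophages that overlaps 1010001N08Rik, Timd4, a receptor for phosphatidylserine, and Abca1, a cholesterol exporter, were not called. Interferon response genes differed in direction between recipients. With labelled Gls1-null marrow, 21 of 23 lay above 0 in Gls2-intact recipients (median 0.34, adjusted p = 5.54e-06, adjusted p = 0.853 with an estimated correlation), and 19 of 23 lay below 0 in Gls2-null recipients (median -0.69, adjusted p = 3.12e-11, adjusted p = 0.535 with an estimated correlation). The first call was lost without replicate 2 of the Gls2-intact recipients of Gls1-null marrow (0.22, adjusted p = 0.0597). The interaction had a median of -1.17 (20 of 23 below 0, 2 adjusted over the list alone, adjusted p = 3.65e-18, adjusted p = 0.21 with an estimated correlation). As examples chosen after their values were seen, Irf7 was 96.8 ± 13.3 CPM with Gls1-null and 55.7 ± 12.6 CPM with control marrow in Gls2-intact recipients, and Oas3, a sensor of double-stranded RNA (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661), was 15.9 ± 5.35 and 47.7 ± 13.5 CPM in Gls2-null recipients.

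Other lists called in Gls2-null recipients rested on single libraries. With labelled Gls1-null marrow, efferocytosis (-0.32, adjusted p = 7.59e-06), lipid-associated macrophages (-0.28, 0.0121), Nrf2 and redox genes (-0.22, 0.0193) and large peritoneal macrophages (-0.28, 0.00169) were lower, and T and NK cells (1.33, 5.04e-05) and mast cells and eosinophils (0.40, 0.00169) were higher, all with adjusted p = 0.551 with an estimated correlation. Large peritoneal macrophages were not called among genes without opposite-strand exons (0.153). Without replicate 1 of the Gls2-null recipients of Gls1-null marrow, efferocytosis (-0.10, adjusted p = 0.432), lipid-associated macrophages (-0.07, 0.985), Nrf2 and redox genes (0.294) and mast cells and eosinophils (0.69, 0.106) lost their call, and the medians of large peritoneal macrophages (0.07) and T and NK cells (-0.99) changed sign. Without its replicate 2, efferocytosis was -0.67, lipid-associated macrophages -0.64, large peritoneal macrophages -0.74 and T and NK cells 2.01. Replicate 3 of the Gls2-null recipients of control marrow ended the calls of lipid-associated macrophages (-0.11, 0.298), Nrf2 and redox genes (-0.11, 0.375), large peritoneal macrophages (0.063) and mast cells and eosinophils (-0.09, 0.687), and replicate 2 of the Gls2-null recipients of Gls1-null marrow those of Nrf2 and redox genes (-0.35, 0.0825) and mast cells and eosinophils (0.158). The median of mast cells and eosinophils was 0.86 and 0.83 without replicates 1 and 2 of the Gls2-null recipients of control marrow. The share of ribosomal RNA genes moved with this group, at 2.16 ± 0.143% of counts in Gls2-null recipients of Gls1-null marrow against 0.965 ± 0.0668% with control marrow. In Gls2-intact recipients, the medians of lists not called included -0.04 for the cell cycle, -0.12 for glutamine metabolism, 0.03 for cholesterol synthesis, 0.15 for inflammatory NF-kB targets, -0.08 for amino acid stress, 0.00 for B cells, 0.04 for dendritic cells and -1.78 for erythroid cells (adjusted p = 0.329 to 0.996). Only 2 markers of mesothelium and fibroblasts were measured (median -1.19, not tested).

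Recipients labelled Gls2-null were compared with Gls2-intact recipients for the effect of the recipient's label. With control marrow (n = 3 and 2), edgeR called 0 genes (751 at an unadjusted p under 0.05) and DESeq2 called 4. Genes of the respiratory chain had lower medians, with 44 of 55 nuclear oxidative phosphorylation genes below 0 (median -0.35, adjusted p = 1.09e-06, adjusted p = 0.908 with an estimated correlation) and 10 of 10 mitochondrial genes below 0 (-0.80, 1.09e-07, adjusted p = 0.908 with an estimated correlation). Both lists kept their calls in every omission, with medians of -0.23 for the nuclear genes without replicate 2 of the Gls2-intact recipients of control marrow and -0.51 for the mitochondrial genes without replicate 2 of the Gls2-null recipients. Examples chosen after their values were seen were mt-Nd4l (-1.43 ± 0.43, from 27.4 ± 8.11 to 10.0 ± 4.78 CPM) and Cox8a, a subunit of complex IV (-1.27 ± 0.50). Interferon response genes were not called (-0.28, adjusted p = 0.0674).

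With labelled Gls1-null marrow (n = 2 and 2), edgeR called 0 genes between Gls2-null and Gls2-intact recipients (1173 at an unadjusted p under 0.05), and DESeq2 called 14. Without replicate 1 of the Gls2-null recipients edgeR called 26, and without replicate 2 it called 7. All 23 interferon response genes lay below 0, with 0 called over all genes and 15 adjusted over the list alone (median -1.26, adjusted p = 4.41e-22, adjusted p = 0.138 with an estimated correlation), and the list kept its call in every omission. Irf7 was 28.6 ± 1.33 against 96.8 ± 13.3 CPM (-1.76 ± 0.29, adjusted p = 0.207), and Oas3 15.9 ± 5.35 against 48.1 ± 0.131 CPM (-1.61 ± 0.33, adjusted p = 0.469). Nuclear oxidative phosphorylation genes (median -0.55, 49 of 55 below 0, adjusted p = 6e-08) and the mitochondrial genome (10 of 10 below 0, 6.17e-07) were lower, the second by a median of 1.00 on the log2 scale, both with adjusted p = 0.741 with an estimated correlation. Leaving out replicate 1 of the Gls2-intact recipients of Gls1-null marrow moved these medians to -0.26 and -0.43. Their interactions of marrow and recipient were not called (-0.03, adjusted p = 0.239, and -0.27, adjusted p = 0.663). Efferocytosis (-0.27, 0.00413), lipid-associated macrophages (-0.44, 0.00413), large peritoneal macrophages (-0.31, 0.00805) and T and NK cells (1.40, 0.0159) were called, with adjusted p = 0.741 to 0.77 with an estimated correlation, but large peritoneal macrophages were not called among genes without opposite-strand exons (0.0514). These calls were lost without replicate 1 of the Gls2-intact recipients (medians -0.06, -0.16, -0.10 and 1.13). Without replicate 1 of the Gls2-null recipients, efferocytosis (0.01) and lipid-associated macrophages (-0.21) were not called, and the other medians changed sign (0.09 and -1.01). The medians of the 4 lists were -0.71, -0.81, -0.94 and 2.14 without replicate 2 of the Gls2-null recipients, and those of the first 3 were -0.64, -0.71 and -0.48 without replicate 2 of the Gls2-intact recipients. The ribosomal RNA share was 2.16 ± 0.143% against 1.47 ± 0.511%.

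**Figure D5:**
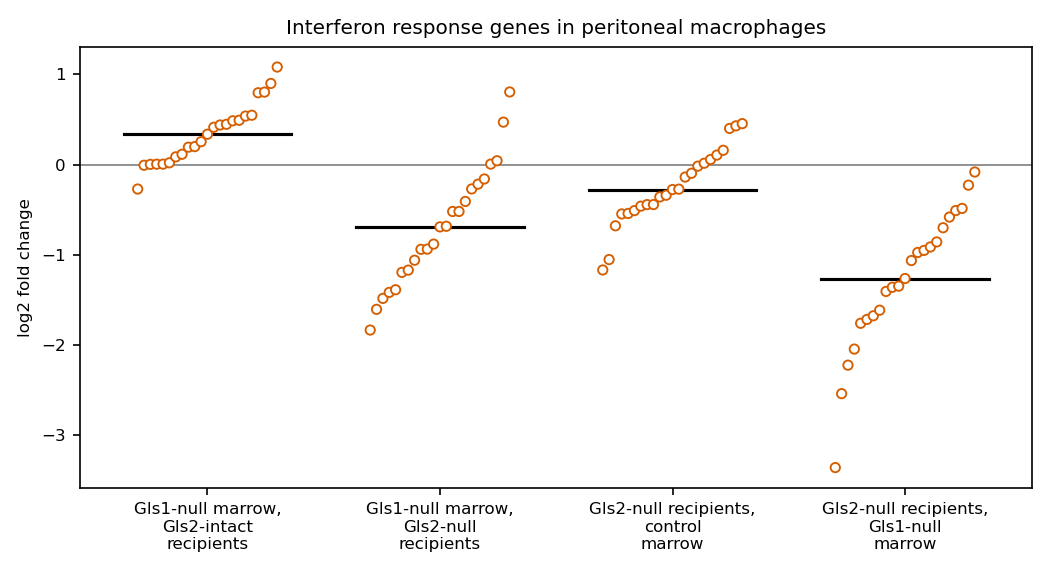
Log2 fold (vertical axis) of 23 interferon response genes in the marrow and recipient comparisons of peritoneal macrophages. The medians were 0.34 and -0.69 for labelled Gls1-null marrow in Gls2-intact and Gls2-null recipients, and -0.28 and -1.26 for Gls2-null recipients of control and Gls1-null marrow.

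Mice labelled with both losses were compared with mice with neither (n = 2 and 2), which asked for the joint effect. EdgeR called 0 genes (1049 at an unadjusted p under 0.05) and DESeq2 called 3. EdgeR called 23 without replicate 1 and 6 without replicate 2 of the mice with both losses. Interferon response (-0.93, 22 of 23 below 0, adjusted p = 2.6e-12, 8 adjusted over the list alone) and nuclear oxidative phosphorylation (-0.41, 49 of 55 below 0, 4.58e-06) had lower medians and kept their calls in every omission, but none of the 6 lists called here was called with an estimated correlation (adjusted p = 0.412 to 0.678 with an estimated correlation). The mitochondrial genome was lower (-0.91, 4.58e-06), but was lost without replicate 1 of the mice with both losses (-0.65, 0.115), and had a median of -0.59 without replicate 2 of the mice with neither. Efferocytosis (-0.29, 0.0321), lipid-associated macrophages (-0.43, 0.00291) and large peritoneal macrophages (-0.49, 0.00398) were lower, but the first and the last were not called among genes without opposite-strand exons (adjusted p up to 0.107). Leaving out replicate 1 of the mice with both losses ended the calls of the first 2 (0.04, 0.979, and -0.30, 0.45) and turned the sign of the last (0.03), while leaving out replicate 2 moved the 3 medians to -0.74, -0.77 and -0.99. Efferocytosis (-0.15, 0.346) and large peritoneal macrophages (-0.20, 0.367) were also lost without replicate 1 of the mice with neither. The ribosomal RNA share was 2.16 ± 0.143% against 1.18 ± 0.185%.

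The interaction of marrow and recipient asked whether the labelled Gls1 loss acted differently where Gls2 was labelled lost. EdgeR called 0 genes (178 at an unadjusted p under 0.05) and DESeq2 called 1, and without replicate 1 of the mice with both losses edgeR called 4. Besides the interferon response, efferocytosis (-0.40, adjusted p = 1.87e-05), large peritoneal macrophages (-0.24, 0.0371), T and NK cells (1.45, 2.46e-04) and mast cells and eosinophils (0.69, 0.00358) were called, with adjusted p up to 0.886 with an estimated correlation, but large peritoneal macrophages were not called among genes without opposite-strand exons (0.291). Only the interferon response kept its call in every omission. Leaving out replicate 1 of the mice with both losses ended the call of efferocytosis (-0.21, 0.229) and turned the sign of large peritoneal macrophages (0.22) and T and NK cells (-0.87). Leaving out their replicate 2 moved these 3 medians to -0.83, -0.85 and 2.29, and ended the call of mast cells and eosinophils (0.138). Replicate 1 of the Gls2-intact recipients of Gls1-null marrow ended the calls of efferocytosis (-0.15, 0.0682), large peritoneal macrophages (-0.06, 0.873), T and NK cells (0.0748) and mast cells and eosinophils (0.0748), and their replicate 2 moved efferocytosis to -0.62. The call of large peritoneal macrophages was also lost without replicate 2 of the mice with neither (-0.04, 0.635) or replicate 2 (0.0759) or 3 (-0.11, 0.289) of the Gls2-null recipients of control marrow, and its median was -0.55 without replicate 1 of the mice with neither. That of mast cells and eosinophils was lost without replicate 2 of the mice with neither (0.0563) or replicate 3 of the Gls2-null recipients of control marrow (0.20, 0.289), and its median was 1.13 and 1.09 without replicates 1 and 2 of that group. T and NK cells had a median of 2.30 without replicate 1 of that group.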

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

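The tests of counting without regard to strand, of antisense RNA of the cells, of the share of counts in genes with opposite-strand exons and of the markers of large peritoneal macrophages were chosen only after the results were seen, as were the fits without opposite-strand exons and without the libraries with Ddx3y counts.

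Genes with opposite-strand exons held at least 89.4% of the counts of each marrow-derived library, although they are 16.9% of genes. Counting without regard to strand cannot give a gene that lies wholly in exons of an opposite-strand partner more counts than the partner, and of 476 such genes those above their partner held at least 4.18% of each marrow-derived library, which argues against it. Antisense RNA of the cells would leave mt-Nd6 below the heavy-strand genes, and its lowest ratio to them over the 29 libraries was 40.0, which argues against it. Libraries counted on the strand opposite to the transcripts would make non-coding genes follow their coding partners, and of 149 non-coding genes called with IL-4 in Gls1-null cells, 108 (72.5%, exact 95% interval 64.6% to 79.5%) had the sign of the partner, which is consistent with such counting. The strand setting is not stated and stays open as the source, in which case genes without a partner hold only residual counts, and no other biological explanation was tested.

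Genes of the mitochondrial genome were higher in Gls1-null cells with IL-4 and MSO by a median of 0.81, and the difference from the effect with IL-4 alone drew attention through the genotype by MSO interaction (0.55, adjusted p = 3.12e-04, with 1.88e-05 to 0.0212 over the omissions and up to 0.177 over the other alternatives). A different share of overlapping genes between libraries is argued against by the median of 1.00 among genes without opposite-strand exons (adjusted p = 8.73e-13, and up to 0.00254 over all alternatives other than omissions), and a single library by medians of 0.75 to 0.89 in the 6 omissions (adjusted p up to 9.13e-08). The sex of the cells is argued against by the median of 0.78 without the libraries with Ddx3y counts. For the interaction, 11 of 100 regroupings of the 12 libraries, the real one included, gave a list p as small as 1.73e-05. The smallest other was 6.35e-09. Regroupings can hold the genotype effect, so chance stays open. Loss of Gls1 when glutamine synthesis is blocked stays open as a hypothesis, and a library batch, which the labels do not give, was not tested.

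Interferon response genes had a lower median in labelled Gls2-null recipients of Gls1-null marrow (-1.26), with 0 of 23 called. They stood out because the effect of marrow differed between recipients (interaction -1.17, adjusted p = 3.65e-18). With an estimated correlation, adjusted p was 0.138, and 0.21 for the interaction. A single library is argued against by medians of -1.46 to -1.13 in the 4 omissions. Fewer macrophages would lower their markers as much. The 17 large peritoneal macrophage markers had a median of -0.31 (bootstrap over genes -0.56 to -0.11). It was 0.09 and -0.94 without replicates 1 and 2 of the Gls2-null recipients, so this stays open. The labelled loss of Gls2, a batch or the health of the mice behind the 2 samples in each group stay open. Gls and Gls2 folds where labelled lost were smaller than their errors, and the ribosomal RNA share moved with the group.

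Other results drew attention because an interaction was called, and no explanation was tested for them. In the genotype by MSO interaction, these were Gm47428 (1.20, adjusted p = 0.0246), the lipid-associated list (-0.46, adjusted p = 8.01e-04, with up to 0.132 over the omissions and 0.975 over the other alternatives) and Nrf2 and redox genes (-0.41, adjusted p = 0.0497, with up to 0.274 and 0.944). In the marrow by recipient interaction, these were efferocytosis (-0.40, adjusted p = 1.87e-05, with up to 0.229 over the omissions), large peritoneal macrophages (-0.24, 0.0371, with up to 0.873), T and NK cells (1.45, 2.46e-04, with up to 0.0748) and mast cells and eosinophils (0.69, 0.00358, with up to 0.289), and each reached 0.886 with an estimated correlation. Replicate 1 of the Gls2-null recipients of Gls1-null marrow decided the sign of large peritoneal macrophages (0.22 without it) and of T and NK cells (-0.87 without it).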

How the results depend on the processing

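The fit of genes without opposite-strand exons and the fit without the 4 Gls1-null libraries with Ddx3y counts were chosen after the data were seen, and the other alternatives were planned. Among the alternatives other than the omission of 1 library, 71 of the counts of called genes and lists stayed within 1.5 times and 43 did not, 2326 values of named genes kept their call or, where not called, stayed within 1 standard error, 129 lost the call, 38 gained it and 60 moved further, and 77 list calls were kept, 110 lost and 1 changed sign. Over the omissions these numbers were 91 and 41 for counts, 1743, 326, 23 and 215 for named genes, and 279, 89 and 7 for list calls. With only genes without opposite-strand exons, which are fewer and hold fewer counts, the calls numbered 71 and 119 for IL-4 in control and Gls1-null cells, 0, 2, 14 and 16 for Gls1-null against control in basal, IL-4, MSO and IL-4 with MSO cells, 0 and 1 for MSO in basal control and Gls1-null cells, 0 and 0 for MSO with IL-4 in control and Gls1-null cells, and 0 for the genotype by MSO interaction by edgeR. The unadjusted counts in the fit of all genes were 776 for the basal genotype comparison, 686 and 139 for MSO with IL-4 and 396 for that interaction. In peritoneal macrophages that fit also called small peritoneal macrophages for Gls2-null recipients of control marrow (-0.52), Nrf2 and redox genes for those of Gls1-null marrow (-0.43) and the interaction (-0.33), and T and NK cells for both losses (1.15). DESeq2 size factors gave 1 call for basal Gls1-null against control. Without a filter on low counts, there were 16 calls for Gls1-null against control in basal and 44 in IL-4 cells, 10 for MSO in basal Gls1-null cells, 4 for the genotype by MSO interaction, and in peritoneal macrophages 29 for Gls1-null marrow in Gls2-null recipients, 74 and 180 for Gls2-null recipients of control and Gls1-null marrow and 158 for both losses. The DESeq2 Wald test gave 21, 45 and 74 calls for Gls1-null against control in basal, IL-4 and MSO cells, 1 for MSO in basal Gls1-null cells, 35 for MSO in IL-4 control cells, 0 for the genotype by MSO interaction, and in peritoneal macrophages 4 for Gls1-null marrow in Gls2-null recipients, 4 and 14 for Gls2-null recipients of control and Gls1-null marrow, 3 for both losses and 1 for the interaction. Without the libraries with Ddx3y counts, there were 298 calls for IL-4 in Gls1-null cells, 1, 95 and 125 for Gls1-null against control in basal, MSO and IL-4 with MSO cells, 25 for MSO in IL-4 control cells and 11 for the genotype by MSO interaction, and the glycolysis list changed sign for MSO in basal Gls1-null cells (0.0805, adjusted p = 0.781, with -0.63 to -0.06 and adjusted p = 5.60e-04 to 0.557 over the omissions). A fit of only the 2 groups compared gave 88 and 79 calls for Gls1-null against control in IL-4 and IL-4 with MSO cells, 19 and 5 for MSO in IL-4 control and Gls1-null cells and 2 for Gls2-null recipients of control marrow. An estimated correlation left 5 of 72 list calls. The cause of these changes was not tested beyond the smaller number of genes and counts. With the replicate number as a block, the calls were 321 and 617 for IL-4 in control and Gls1-null cells, 5, 32, 50 and 52 for the 4 genotype comparisons and 0, 0, 10 and 2 for the 4 MSO comparisons, and with a block within genotype 362 and 717 for IL-4 and 18 for MSO in basal Gls1-null cells. The residuals did not show that replicate numbers pair the libraries, since the correlation of residuals between libraries of 1 number was -0.17 to 0.15 over 24 pairs (median 0.02) and in 10 of the 24 the library of the same number was the closest. However, the Gls1-null library with Ddx3y counts was number 2 in both groups without IL-4 and 3 in both with it. No paired analysis was possible because the labels of the peritoneal macrophages give no donor or litter. Leaving out 1 library gave 208 to 289 and 310 to 734 calls for IL-4 in control and Gls1-null cells, 0 to 192, 2 to 46, 2 to 28 and 17 to 50 for Gls1-null against control in basal, IL-4, MSO and IL-4 with MSO cells, 0 to 1 and 0 to 390 for MSO in basal control and Gls1-null cells, 0 to 15 and 2 to 2 for MSO with IL-4, 0 to 9 and 0 to 3 for the genotype by IL-4 and by MSO interactions, and in peritoneal macrophages 0 to 0 and 0 to 24 for Gls1-null marrow in Gls2-intact and Gls2-null recipients, 0 to 0 and 0 to 26 for Gls2-null recipients of control and Gls1-null marrow, 0 to 23 for both losses and 0 to 4 for the interaction. The called lists numbered 66 to 87. Without replicate 1 of the Gls2-null recipients of Gls1-null marrow, the large peritoneal macrophage list changed sign to 0.0744 for Gls1-null marrow in Gls2-null recipients, 0.0860 for Gls2-null recipients of Gls1-null marrow, 0.0339 for both losses and 0.222 for the interaction (adjusted p = 0.389, 0.801, 0.847 and 0.301), with lowest medians over the omissions of -0.74, -0.94, -0.99 and -0.85 and adjusted p from 1.27e-08, 9.92e-08, 1.92e-08 and 4.97e-07. The T and NK cell list changed sign to -0.99, -1.01 and -0.87 for the first 2 and the interaction (adjusted p = 0.0243, 0.0322 and 0.0445), with highest medians of 2.01, 2.14 and 2.30 and adjusted p up to 0.0383, 0.194 and 0.0748. The cause of these changes of sign was not tested. At these depths, changes of 1 on the log2 scale were recovered in 36% to 38% of simulated genes in marrow-derived and 6% to 14% in peritoneal macrophages, so genes not called in peritoneal macrophages are not shown to be unchanged.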

Other observations

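The tests of the Lyz2 alleles and the genes of this part were chosen only after the results were seen. Counts assigned to Tbc1d17 (chromosome 7, 44834623 to 44849079), a regulator of vesicle traffic, rose with IL-4. They went from 35.2 ± 14.9 to 1102 ± 78.3 CPM in Gls1-null cells (log2 fold 4.99 ± 0.44, and 4.07 ± 0.47 in controls). It shares 3423 bp of exons with Il4i1, an amino acid oxidase induced by IL-4, on the opposite strand. Each gene's counts can belong to the other. Il4i1 was not called with IL-4 (1.23 ± 0.47 in control and 0.89 ± 0.47 in Gls1-null cells). Tbc1d17 was higher in Gls1-null than in control cells with IL-4 (1102 ± 78.3 against 331 ± 125 CPM, adjusted p = 0.0292) and with IL-4 and MSO (1079 ± 274 against 273 ± 82.6 CPM, adjusted p = 0.00737). The first call was lost without IL-4 control replicate 3 (0.105) or IL-4 Gls1-null replicate 1 (0.111), 2 (0.0944) or 3 (0.142), and its genotype by IL-4 interaction was not called (0.92 ± 0.65, adjusted p = 0.975).

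Lyz2 was lower in Gls1-null marrow-derived cells, and a candidate explanation is that 1 of its alleles is interrupted in the Gls1-null line, as in mice that carry Cre in this gene. Such an allele would lower Lyz2 in all 6 genotype comparisons on genes without opposite-strand exons, and the folds ranged from -1.14 to -0.0679. They were -0.58 ± 0.22 in basal, -1.14 ± 0.19 in IL-4, -1.10 ± 0.23 in MSO and -0.92 ± 0.19 in IL-4 with MSO cells, with errors of 0.42 and 0.39 about -0.0679 and -0.62 in peritoneal macrophages of Gls2-intact and Gls2-null recipients of labelled Gls1-null marrow. The wide error in peritoneal macrophages keeps the question open, and the labels do not say how Gls1 was deleted.

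Splits of the 6 libraries into other groups of 3 were tested where both groups had 3. The 10 splits are too few for a share under 0.05. The real split alone, 1 of 10, reached its count in each of 4 comparisons. It called 24 genes for Gls1-null against control with IL-4 (highest other 0), 45 with IL-4 and MSO (0), 10 for MSO in IL-4 control cells (1) and 2 in IL-4 Gls1-null cells (0). For the genotype by MSO interaction, 6 of 100 regroupings of the 12 libraries, the real one included, called at least the 1 gene. The highest other called 21. Such a count points to a structure of the samples, which can include the effect of genotype and was not examined. Chance therefore stays open.

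Xist, which overlaps Tsix, had no count and Ddx3y had 2 to 3 counts in 4 Gls1-null marrow-derived libraries, which were basal replicate 2, MSO replicate 2, IL-4 replicate 3 and IL-4 with MSO replicate 3. The other 16 marrow-derived libraries had 4 to 19 Xist counts and 0 Ddx3y counts. Each peritoneal library had 129 to 185 Xist and 10 to 26 Ddx3y counts. The labels give no sex.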
